A study of Homo sapiens with 14 samples.

How the data were processed

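The series holds ChIP-seq peak lists of DU145 cells with a stable EED knockdown and of control cells with a scramble construct, selected with puromycin. There are 14 libraries and 14 groups, 1 library for each of 7 antibodies in each cell line. Per the labels' protocols, 10 to 20 ng of precipitated DNA entered each library, libraries were sequenced with 40-nucleotide reads on an Illumina HiSeq instrument, and each had a lane of its own. Reads were aligned with Bowtie to hg19, per the submitters' processing notes. The version of Bowtie and its settings are not given in the sources used here. The deposited lists carry the name of the HPeak peak caller, and whether an input or IgG library was used in calling is not given in the sources used here. Peaks were called per library, 1 list for each, as the deposited lists show.

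Each deposited list gives, without a header, a chromosome, start, end, length, an offset within the peak, a height and a score. The height is taken here as the signal of a peak as the authors' caller wrote it. Its meaning was inferred from its values: it is never negative, and 98.0% to 100.0% of heights per library lie within 0.001 of a whole number less a multiple of a constant of that library. The score in the deposited lists is negative, was not used in any comparison, and its definition is not given in the sources used here. Lengths are multiples of 25 bp in every list and no peaks overlap within a list. Heights were used to rank or filter peaks, and they were compared between libraries only in the stricter threshold and in a check of tall peaks. Read totals are not given in the sources used here, so depth per library is unknown and precision is limited by the number of peaks, from 1372 to 56011 per library.

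Chromosomes are written as bare numbers in the lists of EED and both uH2A antibodies, and with a prefix in the lists of RING1A, RING1B, BMI1 and H3K27me3. Numbers after the autosomes were read as X and Y, which is an assumption. The same split separates the culture descriptions in the labels and the presence of peaks with a height of 0, which only the second set has. It was treated as a technical batch of 2 library sets. Both sets hold control and knockdown libraries of each of their antibodies.

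Overlap meant at least 1 bp in common. A control peak was kept when it overlapped a knockdown peak of the same antibody and lost otherwise, and a knockdown peak without a control peak was new. Ratios of peak numbers carry exact conditional intervals, shares carry Clopper-Pearson intervals and differences of shares Newcombe intervals, at the 95% level. These cover counting error only, treat peaks as independent, and say nothing of the variation between cultures. No p-value between conditions was computed, since each group has 1 library. Overlap was set against 200 random placements of 1 list, each peak staying on its chromosome up to the largest end seen in any list. Heights were split into 4 equal classes, of 25% of the peaks each, within each control library. The overlap count was tested on simulated lists with a planted share of kept peaks, and the share recovered was within 0.103 percentage points of the planted one for 7 of 7 antibodies, each at its number of control peaks.

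H3K27me3-dense windows are 100-kb windows with at least 5 kb covered by control H3K27me3 peaks. High-signal windows are 100-kb windows, with their neighbours, in which at least 2 antibodies other than the one tested have a peak over 10 times the median height of the library. Both definitions were chosen after the data were seen. The comparisons of peak number, kept peaks, co-occupancy and loss at shared sites, their alternatives other than those named as added, and the rule for naming regions were fixed before the data were examined. The rule took, per antibody, the 3 tallest lost, 2 tallest kept and 1 tallest new peak, and the 10 regions bound by all 7 antibodies with the highest summed rank. The windows named among the 20 densest, and the chromosomes named for their density, were chosen after their values were seen.

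The alternatives were a stricter height threshold, merging of peaks within 1000 bp, autosomes only, covered length in place of number, overlap of at least 50% of a peak, peaks within 1000 bp, equal numbers of peaks, and random shifts of at most 500000 bp. Peaks outside high-signal windows, peaks of height above 0 and a higher minimum for dense windows were added after the data were seen. Results on promoters, on fixed gene lists and on named Polycomb genes had been planned and are not analysed here, because no annotation of hg19 was used and coordinates were not converted between genome builds. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.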

Results

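Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map Polycomb proteins and their histone marks in DU145, an established human prostate cancer cell line. Cells carrying a stable knockdown of EED were set against control cells carrying a scramble construct. The titles of the knockdown libraries all carry the same construct label, so an effect of that construct cannot be told from an effect of EED. EED is a core subunit of Polycomb repressive complex PRC2, which places the H3K27me3 mark and also binds it. RING1A and RING1B are the catalytic ubiquitin ligases of Polycomb repressive complex PRC1, BMI1 is a partner of these ligases, and ubiquitylated histone H2A (uH2A) is the mark they place. The series has 14 libraries, 1 for each of 7 antibodies in each cell line. The antibodies were raised against EED, RING1A, RING1B, BMI1, H3K27me3 and uH2A, the last with a rabbit and a mouse antibody. No library had a replicate, so no difference below has a replicate check, and intervals are 95% intervals that cover counting error only. Read totals are not given in the sources used here and sequencing depth is unknown. Coordinates are hg19, and no gene annotation of that build was used, so regions are named by position alone.

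The first comparison asked whether each antibody marked fewer sites once EED was knocked down. EED itself had 13082 peaks in control cells and 1372 in knockdown cells, a knockdown to control ratio of 0.105 (exact interval 0.0991 to 0.111). H3K27me3, the PRC2 mark, had 35368 control and 4205 knockdown peaks, a ratio of 0.119 (0.115 to 0.123). RING1A showed the lowest ratio of the 7 antibodies, 0.0727 (0.0704 to 0.0751), with 56011 control and 4072 knockdown peaks. BMI1 had 20775 and 6257 peaks (ratio 0.301, 0.293 to 0.310), and RING1B had 5155 and 1739 (ratio 0.337, 0.319 to 0.356). The uH2A mouse antibody had 33879 and 7160 peaks (ratio 0.211, 0.206 to 0.217), and the uH2A rabbit antibody had 27077 and 11327 (ratio 0.418, 0.409 to 0.428), the highest ratio of the 7.

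**Figure D1:**
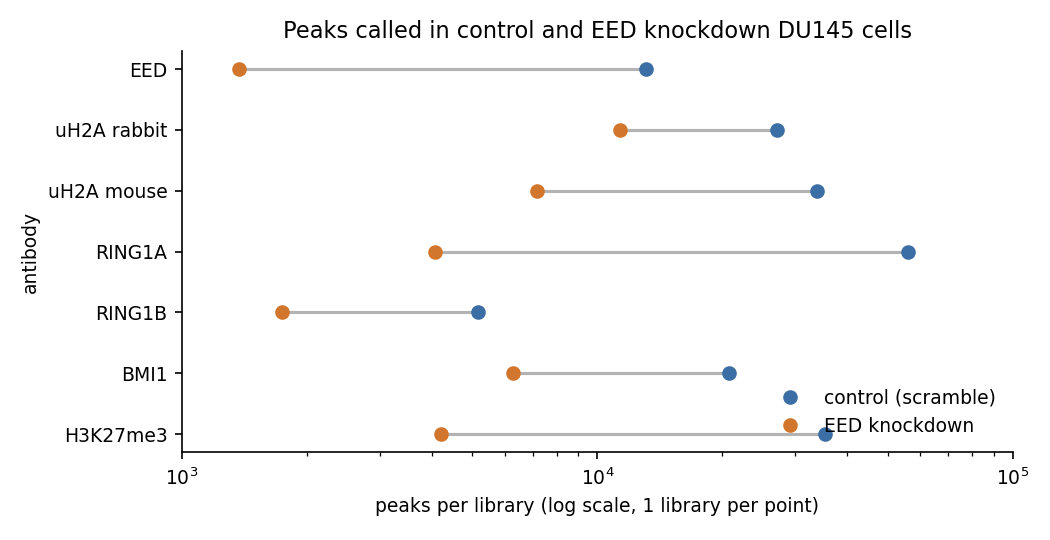
Number of peaks per library (horizontal axis, log scale) for each antibody (vertical axis) in control and EED knockdown DU145 cells; each point is 1 library. The knockdown point lies left of the control point for 7 of 7 antibodies, from 13082 to 1372 peaks for EED and from 27077 to 11327 for the uH2A rabbit antibody.

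The libraries fall into 2 sets that differ in the culture description and in chromosome naming. The set with EED and both uH2A antibodies had fewer knockdown peaks in 3 of 3 antibodies. The set with RING1A, RING1B, BMI1 and H3K27me3 had fewer in 4 of 4. The length covered by H3K27me3 peaks was 10.4 Mb in control and 0.895 Mb in knockdown cells, that of RING1A peaks 9.07 and 0.880 Mb, and that of EED peaks 2.13 and 0.198 Mb. For the uH2A rabbit antibody it was 6.10 Mb in control and 2.99 Mb in knockdown cells, the highest ratio of covered length (0.490). By covered length the lowest ratio was that of H3K27me3 (0.0858), followed by EED (0.0929) and RING1A (0.0970). With peaks restricted to those at least as tall as the median control peak, 4 ratios moved by more than 1.5-fold: RING1B to 0.111, RING1A to 0.0463, uH2A mouse to 0.115 and H3K27me3 to 0.194. Peak height was not normalised between libraries, and all 7 ratios stayed below 1 under that restriction.

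The second comparison asked which control sites still carried a peak of the same antibody in knockdown cells. Few H3K27me3, RING1A and EED sites did: 3.81% of 35368 H3K27me3 peaks (Clopper-Pearson interval 3.61 to 4.01), 4.07% of 56011 RING1A peaks (3.91 to 4.24) and 5.79% of 13082 EED peaks (5.39 to 6.20). The share was 10.7% for uH2A mouse (10.4 to 11.1), 20.7% for RING1B (19.6 to 21.8), 21.1% for BMI1 (20.6 to 21.7) and 28.8% for uH2A rabbit (28.3 to 29.4). Random placement of the knockdown peaks on the same chromosomes gave at most 0.321% in any of 200 draws for any antibody. In the other direction, 75.0% of BMI1 knockdown peaks lay on a control peak, as did 69.8% for uH2A rabbit, 63.9% for RING1B, 60.7% for RING1A, 57.1% for EED and 52.9% for uH2A mouse. H3K27me3 was the lowest at 32.4% (31.0 to 33.8), which left 2843 of its 4205 knockdown peaks at positions without a control H3K27me3 peak. These need not be newly methylated sites, and their overlap with other antibodies was not computed apart from the rest. Of all 4205, 72.2% lay on a knockdown BMI1 peak, 53.9% on RING1A and 31.1% on RING1B. In control cells these shares of H3K27me3 peaks were 5.83%, 9.07% and 3.61%. For EED and uH2A in knockdown cells they were 7.97% to 8.82%. High-signal windows held 16.4% of the knockdown and 1.30% of the control H3K27me3 peaks.

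Taller control peaks were kept more often. Among the tallest 25% of control peaks, 70.3% of uH2A rabbit peaks were kept, against 8.60% among the lowest 25%. BMI1 kept 55.2% of its tallest 25%, RING1B 47.6%, uH2A mouse 25.7%, EED 16.7% and RING1A 12.9%. H3K27me3 kept 6.70% of its tallest 25%, the lowest of the 7 antibodies. The 4 antibodies of the second library set also list peaks with a height of 0, which fall in the lowest 25% and were kept more often than the next 25% by height: 38.0% for BMI1, 36.0% for RING1B, 18.04% for H3K27me3 and 10.0% for RING1A.

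**Figure D2:**
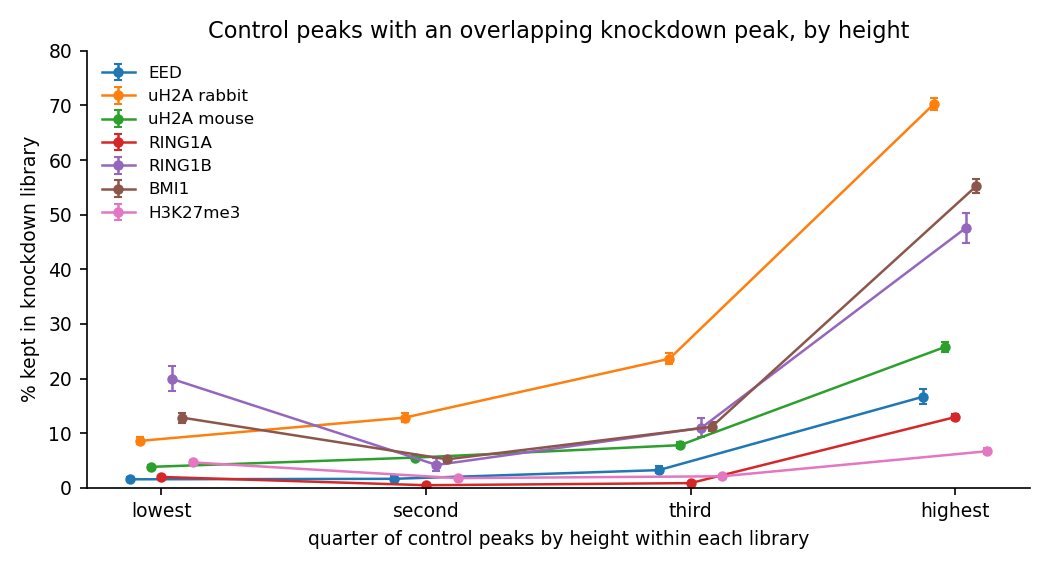
Share of control peaks that overlap a knockdown peak of the same antibody by at least 1 bp (vertical axis, %) by control peak height in 4 equal classes within each library (horizontal axis); bars are 95% Clopper-Pearson intervals. The tallest class ranges from 6.70% for H3K27me3 to 70.3% for uH2A rabbit, and the lowest class of the RING1A, RING1B, BMI1 and H3K27me3 libraries includes peaks of height 0.

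The share kept depends on how many peaks enter. With control peaks limited to the tallest, in the number of the knockdown peaks, it was 28.6% for EED, 36.8% for RING1A, 39.3% for RING1B, 48.5% for BMI1, 28.3% for uH2A mouse, 52.7% for uH2A rabbit and 10.7% for H3K27me3. Other choices lowered some shares by more than 1.5-fold: RING1B to 9.47% with peaks at least as tall as the median control peak, and EED to 3.56% and uH2A mouse to 6.73% with overlaps of at least 50% of the peak. Counting peaks within 1000 bp raised uH2A mouse to 18.6% and RING1A to 6.55%.

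Regions were named by a fixed rule that took, per antibody, the tallest lost, kept and new peaks. The tallest EED peaks lost were on chromosome 14 at 35204151 to 35204425 and at 49717426 to 49718025, and on chromosome 1 at 207097376 to 207097750. The tallest uH2A rabbit peaks lost were on chromosome 9 at 66483851 to 66484225, chromosome 14 at 32479101 to 32479400 and chromosome 20 at 58514151 to 58514625. For uH2A mouse they were on chromosome 21 at 9926226 to 9926550, chromosome 11 at 119612526 to 119612900 and chromosome 1 at 154909001 to 154909425. The tallest RING1B peaks lost were on chromosome 12 at 20704326 to 20704475, chromosome 6 at 119558526 to 119558625 and chromosome 21 at 9700276 to 9700625. Among the 3 tallest H3K27me3 peaks lost was one on chromosome 8 at 144751576 to 144751850, where none of the other 6 antibodies had a peak in either cell line. The others were short peaks of 75 bp, on chromosome 10 at 42385601 to 42385675 and on chromosome 2 at 92315326 to 92315400. The tallest RING1A peaks lost lay on chromosome 10 at 42387201 to 42387275, chromosome 16 at 46403476 to 46403800 and chromosome 3 at 196625576 to 196625750. All 3 of the tallest BMI1 losses lay on chromosome 10, at 42385476 to 42385700, 42392626 to 42392700 and 42529226 to 42529300. Several of these lay beside a knockdown peak of the same antibody without overlapping it. The gap was 25 bp for the first and second of the BMI1 peaks, 25 bp for the RING1B peak on chromosome 21, 50 and 250 bp for the RING1A peaks on chromosomes 10 and 16, and 50 bp for the H3K27me3 peaks on chromosomes 10 and 2. The 3 EED peaks named as lost were at least 7075 bp from a knockdown EED peak.

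Peaks kept at the greatest height gathered in a few places. Their heights were far above the median of their library, such as 12653 against 68.9 for a BMI1 control peak on chromosome 10. No input or IgG library was used here, so these places cannot be told from regions that give signal with any antibody. The EED and uH2A mouse peaks on chromosome 21 at 9826926 to 9827550 and 9826901 to 9827550 were kept, with peaks of 6 of 6 other antibodies in both cell lines. Kept peaks of EED, uH2A rabbit and uH2A mouse also lay on chromosome 1 near 121484576 to 121485400. A stretch of chromosome 10 held kept peaks of uH2A rabbit (42599526 to 42599975), RING1A (42599451 to 42600175 and 42384901 to 42385300), RING1B (42596851 to 42597275 and 42599451 to 42600175), BMI1 (42599426 to 42600275 and 42384901 to 42385425) and H3K27me3 (42596826 to 42597350). H3K27me3 also kept a peak on chromosome 2 at 133025526 to 133026025. The tallest new peaks were on chromosome 6 for EED (58779001 to 58779375) and uH2A rabbit (58778801 to 58779375), chromosome 19 for uH2A mouse (51357876 to 51358125), chromosome 18 for RING1A (107101 to 109025), chromosome 1 for RING1B (121484451 to 121484625), chromosome 4 for BMI1 (49512101 to 49512375) and chromosome 10 for H3K27me3 (42392626 to 42392700). The new H3K27me3 peak lay 25 bp from a control H3K27me3 peak, and the new RING1B peak 500 bp from a control RING1B peak.

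The third comparison asked how far the antibodies shared sites in control cells. RING1B and BMI1 peaks often lay on peaks of another PRC1 protein: 85.7% of RING1B peaks lay on a BMI1 peak (84.7 to 86.7) and 71.9% on a RING1A peak (70.6 to 73.1), and 60.1% of BMI1 peaks lay on a RING1A peak (59.5 to 60.8). In the other direction the longer lists gave lower shares, with 6.11% of RING1A peaks on RING1B, 21.8% of RING1A peaks on BMI1 and 19.8% of BMI1 peaks on RING1B. EED overlapped uH2A, RING1A and BMI1 more often than H3K27me3. Of 13082 EED peaks, 50.7% lay on a uH2A rabbit peak, 36.3% on RING1A, 33.8% on uH2A mouse and 27.5% on BMI1, while 5.22% lay on RING1B and 5.40% on H3K27me3 (5.02 to 5.81). The overlap of EED with H3K27me3 was 8.75-fold that of random placement, and with uH2A rabbit 112-fold.

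**Figure D3:**
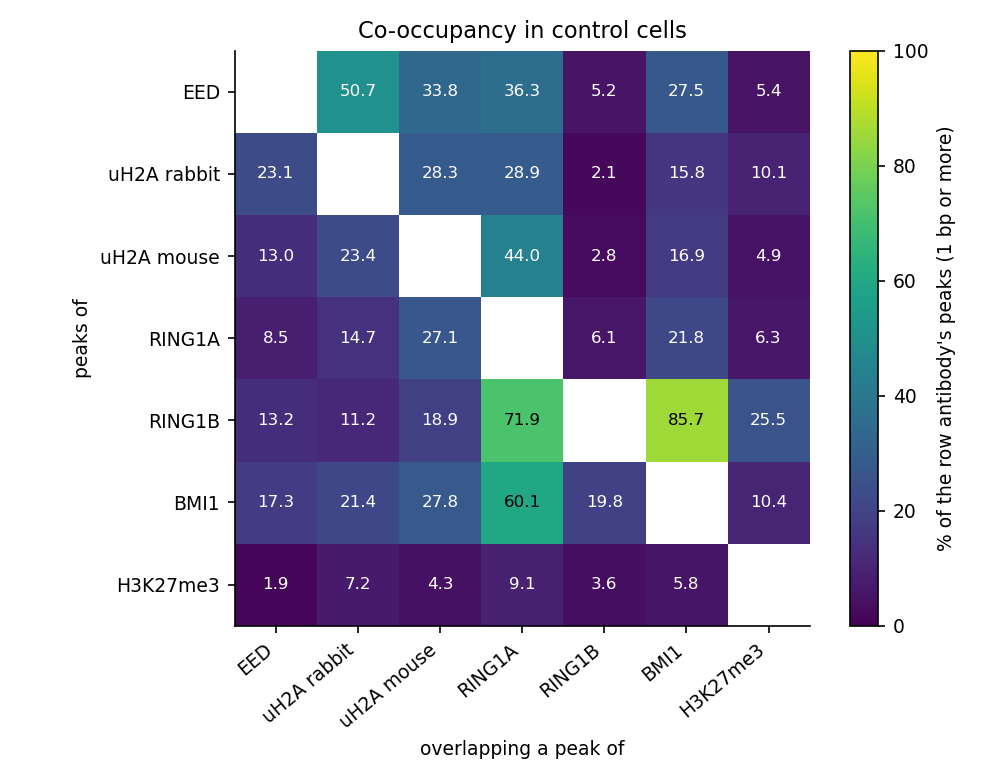
Percentage of each row antibody's control peaks that overlap a peak of the column antibody by at least 1 bp, with the value in each cell and the diagonal left blank. RING1B with BMI1 has the highest value, 85.7%, and H3K27me3 with EED the lowest, 1.92%.

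H3K27me3 peaks seldom met another antibody's peak. RING1A peaks overlapped 9.07% of them, uH2A rabbit 7.17%, BMI1 5.83%, uH2A mouse 4.31%, RING1B 3.61% and EED 1.92%. Of the RING1B peaks, by contrast, 25.5% lay on H3K27me3, as did 10.4% of BMI1, 10.1% of uH2A rabbit, 6.28% of RING1A and 4.94% of uH2A mouse peaks. The 2 uH2A antibodies shared a minority of sites: 28.3% of rabbit peaks lay on a mouse peak and 23.4% of mouse peaks on a rabbit peak. The uH2A mouse peaks met RING1A more often, at 44.0%.

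In control cells the median overlap was 22.5% over 18 ordered pairs within a set and 13.95% over 24 pairs between sets, and in knockdown cells 41.2% and 7.99%. These medians pool 2 unlike sets. In control cells overlaps ran from 13.0% to 50.7% in the EED and uH2A set and from 3.61% to 85.7% in the other. In knockdown cells they ran from 4.48% to 38.5% in the EED and uH2A set, where uH2A mouse on EED had 4.79%. In the other set they ran from 19.5% to 79.9%. An effect of the set cannot be told from that of the antibodies it holds, such as RING1A, RING1B and BMI1. EED and H3K27me3 lie in different sets. EED nevertheless overlapped RING1A (43.2-fold over random) and BMI1 (83.2-fold) of the H3K27me3 set, and H3K27me3 overlapped RING1A of its own set 9.46-fold. Against random shifts of at most 500000 bp, which keep the local density of peaks, the overlap of EED was 3.04-fold with H3K27me3, 25.5-fold with uH2A rabbit, 11.1-fold with RING1A and 19.0-fold with BMI1, and that of H3K27me3 with RING1A 3.55-fold, all below the values from placement along the whole chromosome.

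Merging the control peaks of all antibodies gave 126974 regions, of which 72.5% were bound by 1 antibody only and 115 by all 7. Bound means here only that a peak was called. Regions with more antibodies held a knockdown peak of any antibody more often, from 5.43% of regions with 1 antibody to 46.1% with 3, 78.4% with 5 and 115 of 115 with 7. Part of this is built into the count, since a region with peaks of more antibodies has more chances to keep one. No baseline for that was computed, and region length was not matched. The 10 regions bound by all 7 with the highest summed height ranks were on chromosome 10 (42599426 to 42600400, 42395801 to 42396300, 42596776 to 42597350 and 42386751 to 42387350), chromosome 7 (61968576 to 61969550), chromosome 21 (9826851 to 9827550), chromosome 16 (46403451 to 46403900 and 46390726 to 46392350), chromosome 1 (91852751 to 91853125) and chromosome 2 (162137551 to 162139150). Knockdown peaks of all 7 antibodies were present in each, except that 46403451 to 46403900 on chromosome 16 had 6. These 10 are not typical: of the 115 regions, 26 held knockdown peaks of all 7 antibodies.

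The fourth comparison asked whether PRC1 and uH2A sites shared with EED or H3K27me3 were lost more often than the others. With sites shared with either partner pooled, they were kept more often for 5 of 5 antibodies, although RING1B peaks shared with EED alone were not. RING1B kept 42.4% of 1801 shared peaks and 8.97% of 3354 others. That is a difference of 33.4 percentage points (Newcombe interval 31.0 to 35.9), or 23.8 points outside high-signal windows. The difference was 28.0 points for uH2A rabbit (48.1% against 20.1%, interval 26.8 to 29.2), 20.5 for BMI1 (36.3% against 15.8%, 19.0 to 21.9), 14.1 for uH2A mouse (22.5% against 8.35%, 13.0 to 15.3) and 9.48 for RING1A (12.2% against 2.74%, 8.76 to 10.2). Within each of 4 equal classes of control peak height the difference was also above 0 for these 5 antibodies, with the smallest at 0.626 points for RING1A (0.186 to 1.33). The lowest class of RING1A, RING1B and BMI1 includes peaks of height 0, and RING1B had its largest difference there, 46.8 points. Peak length was not matched, and longer peaks can overlap others more easily.

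The order of the partners differed between the PRC1 proteins and the uH2A mark. RING1B peaks shared with H3K27me3 and not EED were kept at 57.5% (1121 peaks), and those shared with EED and not H3K27me3 at 6.97% (488 peaks). The latter share was not above the 8.97% of RING1B peaks shared with neither. On H3K27me3 alone and on EED alone, BMI1 gave 52.4% and 25.3%, and RING1A 18.4% and 5.80%. The uH2A antibodies had the opposite order, with 24.9% on H3K27me3 alone and 55.6% on EED alone for rabbit, and 13.2% and 23.1% for mouse. In each case the higher share was at sites shared with the partner from the same library set. Counting only overlaps of at least 50% of the peak, the difference was 16.2 points for uH2A rabbit and 8.64 for uH2A mouse, each over 1.5-fold smaller.

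H3K27me3 forms broad domains, and the control H3K27me3 peaks were therefore also summed in 100-kb windows, a choice made after the data were seen. In 529 windows at least 5 kb were covered by control H3K27me3 peaks, 5480.6 kb in all. Knockdown H3K27me3 peaks covered 310.1 kb of these windows, 5.66% of the control length, and 80 windows (15.1%, 12.2 to 18.5) held any. The 2 densest windows and the one ranked 4 lay side by side on chromosome 17, where 77300001 to 77400000, 77200001 to 77300000 and 77100001 to 77200000 had 67375, 52075 and 39575 bp covered in control cells and 0 bp in knockdown cells. Windows on chromosome 6 at 1300001 to 1400000 (38150 bp), chromosome 12 at 132900001 to 133000000 (35975 bp), chromosome 16 at 86300001 to 86400000 (34400 bp) and chromosome 19 at 1700001 to 1800000 (33775 bp) likewise had 0 bp in knockdown cells. Among the 20 densest, 5 held a knockdown H3K27me3 peak, and 2 of these had a knockdown length near or above the control length, on chromosome 1 at 161400001 to 161500000 (27775 and 21050 bp) and, ranked 3, on chromosome Y at 58800001 to 58900000 (40025 bp in control and 53325 bp in knockdown cells).

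Summed peak length differed less between the cell lines for the other antibodies in the same 529 windows. The knockdown length, whether or not at control peaks, as a share of the control length was 13.4% for EED, 19.8% for uH2A mouse, 22.0% for RING1A, 48.6% for uH2A rabbit, 56.2% for BMI1 and 68.2% for RING1B. Fewer windows held a peak: RING1B peaks lay in 89 windows in control and 33 in knockdown cells, BMI1 peaks in 274 and 130, RING1A peaks in 411 and 67, and uH2A mouse peaks in 389 and 186. In the chromosome Y window alone, RING1B peaks covered 10625 bp in control and 45800 bp in knockdown cells, of 256.4 and 174.9 kb in all 529 windows. An EED peak lay in 60.5% of the windows in control cells (56.2 to 64.7) and in 14.6% in knockdown cells (11.7 to 17.9), and a uH2A rabbit peak in 85.3% and 67.3%. On chromosome 17 at 77100001 to 77200000, uH2A rabbit peaks covered 6575 bp in control and 2925 bp in knockdown cells, while EED peaks covered 425 and 0 bp. The windows were chosen by their control H3K27me3 coverage, a choice that can overstate the loss of that antibody in them. Windows in or beside which at least 2 other antibodies had a peak over 10 times the library's median height numbered 9 of the 529, and without them 3.93% of the H3K27me3 length was left. The share left was then 55.2% for RING1B, 49.1% for BMI1, 47.2% for uH2A rabbit, 19.3% for uH2A mouse, 17.8% for RING1A and 11.7% for EED. The chromosome Y window was not among the 9, so the RING1B share still includes it.

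**Figure D4:**
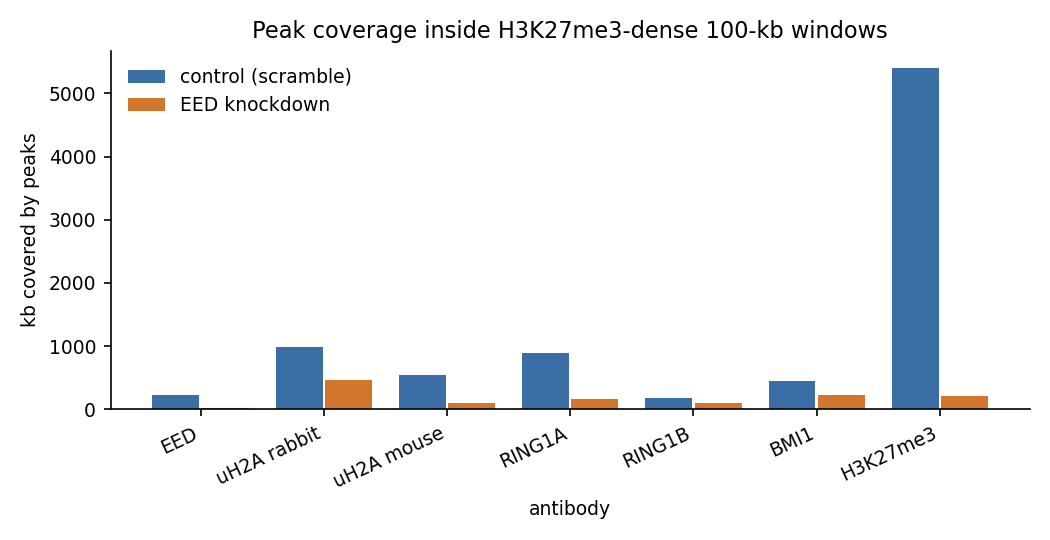
Length covered by peaks (vertical axis, kb, from 0) of each antibody (horizontal axis) inside the 520 H3K27me3-dense windows that lie outside windows of very high signal; each bar is the sum over 1 library, with no error bar. H3K27me3 coverage was 5404 kb in control and 212 kb in knockdown cells.

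Peaks were spread unevenly over chromosomes. Chromosome 14 had the highest density of control peaks for BMI1 (4.61 times the genome's density), RING1A (3.42 times), uH2A mouse (2.85 times) and EED (2.84 times), and the second highest for RING1B (4.44 times), which was densest on chromosome 21. H3K27me3 was densest on chromosome 19 (2.90 times) and uH2A rabbit on chromosome 17 (2.55 times). Control peaks on chromosome X lay between 0.00941 times the genome's density for uH2A mouse and 0.553 times for RING1B, with 0.308 for H3K27me3, where the values for uH2A and EED rest on reading bare chromosome numbers as X. Chromosome 18 held 2242 RING1A control peaks in its first 40 Mb and 81 in the rest, BMI1 1109 and 46, and H3K27me3 456 and 342. On chromosome 9, RING1A had 24 control peaks in the first 30 Mb and 2998 beyond 70 Mb. Peaks per Mb were fewer in the first 30 Mb than beyond 70 Mb in 14 of 14 libraries.

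**Figure D5:**
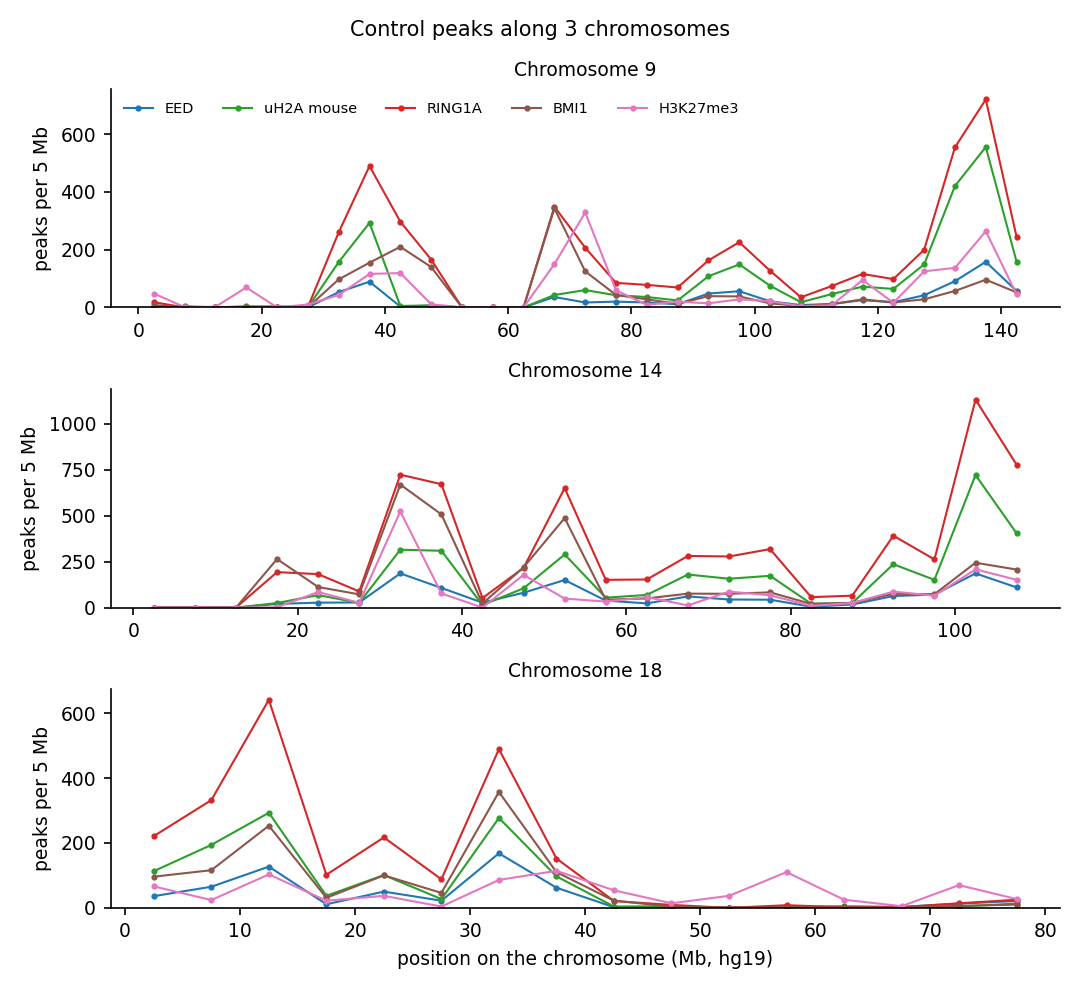
Control peaks per 5-Mb window (vertical axis) along chromosomes 9, 14 and 18 (horizontal axis, Mb, hg19) for 5 antibodies, 1 library each. On chromosome 18 RING1A falls from 2242 peaks before 40 Mb to 81 after it, while H3K27me3 has 456 and 342.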

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

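The alternatives that leave out high-signal windows, peaks of height 0 or windows under 10000 bp were chosen after the results were seen, and the others before. Over 127 alternatives to 32 results, 18 values stayed within the 95% interval of the value given in the text and 109 moved beyond it. None changed direction where a direction was defined. It was not defined for the 39 alternatives of the share kept and the 2 of the dense windows. Ratios of peak numbers stayed below 1, overlaps above random placement and differences in share kept above 0 under every alternative run. The cause was not tested for any value that moved, apart from what the construction of an alternative fixes. Promoter windows of other sizes, a stricter threshold at promoters and another distance for gene lists had been listed beforehand and were not run, since no annotation of hg19 was used. Unknown depth and 1 library per group limit all of these results.

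The ratio of knockdown to control peak numbers was, with the stricter threshold, 0.140 for EED, 0.391 for uH2A rabbit, 0.115 for uH2A mouse, 0.0463 for RING1A, 0.111 for RING1B, 0.257 for BMI1 and 0.194 for H3K27me3. With peaks within 1000 bp merged it was 0.441 for uH2A rabbit, 0.231 for uH2A mouse, 0.0656 for RING1A, 0.306 for RING1B, 0.261 for BMI1 and 0.139 for H3K27me3. On autosomes only it was 0.0681 for RING1A, 0.290 for RING1B, 0.285 for BMI1 and 0.107 for H3K27me3. As covered length it was 0.0929 for EED, 0.490 for uH2A rabbit, 0.179 for uH2A mouse, 0.0970 for RING1A, 0.357 for BMI1 and 0.0858 for H3K27me3. Outside high-signal windows it was 0.0650 for RING1A, 0.285 for RING1B, 0.278 for BMI1 and 0.101 for H3K27me3.

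The share of control peaks kept, in %, was 3.56 for EED, 22.5 for uH2A rabbit, 6.73 for uH2A mouse, 2.75 for RING1A, 16.0 for RING1B, 16.9 for BMI1 and 3.21 for H3K27me3 with an overlap of 50% of the peak. Within 1000 bp it was 7.84 for EED, 36.9 for uH2A rabbit, 18.6 for uH2A mouse, 6.55 for RING1A, 29.7 for RING1B, 29.1 for BMI1 and 4.67 for H3K27me3. With equal numbers of peaks it was 28.6 for EED, 52.7 for uH2A rabbit, 28.3 for uH2A mouse, 36.8 for RING1A, 39.3 for RING1B, 48.5 for BMI1 and 10.7 for H3K27me3. With the stricter threshold in both libraries it was 8.32 for EED, 29.4 for uH2A rabbit, 7.87 for uH2A mouse, 3.11 for RING1A, 9.47 for RING1B, 20.1 for BMI1 and 4.35 for H3K27me3. Outside high-signal windows it was 3.58 for RING1A, 16.2 for RING1B, 19.2 for BMI1 and 2.82 for H3K27me3. Without peaks of height 0 it was 3.83 for RING1A, 18.5 for RING1B, 19.9 for BMI1 and 3.21 for H3K27me3.

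The overlap of EED peaks in control cells, as fold over random, was 11.8 for H3K27me3, 76.0 for RING1A, 94.1 for RING1B, 137 for BMI1, 194 for uH2A rabbit and 114 for uH2A mouse with an overlap of 50% of the peak. With equal numbers of peaks it was 15.4 for H3K27me3, 90.1 for RING1A, 84.1 for RING1B, 122 for BMI1, 243 for uH2A rabbit and 136 for uH2A mouse, and with random shifts 3.04 for H3K27me3, 11.1 for RING1A, 14.1 for RING1B, 19.0 for BMI1, 25.5 for uH2A rabbit and 15.9 for uH2A mouse. The overlap of H3K27me3 peaks was 18.1 for RING1A, 95.8 for RING1B, 37.6 for BMI1, 13.98 for uH2A rabbit and 8.47 for uH2A mouse with an overlap of 50%. With equal numbers it was 29.8 for RING1A, 49.1 for RING1B, 37.0 for BMI1, 22.2 for uH2A rabbit and 12.4 for uH2A mouse, and with random shifts 3.55 for RING1A, 11.5 for RING1B, 5.46 for BMI1, 3.59 for uH2A rabbit and 2.52 for uH2A mouse. For uH2A rabbit peaks on uH2A mouse peaks these settings gave 90.9, 83.9 and 10.0.

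The difference in share kept, in percentage points, was 7.21 for RING1A, 16.0 for BMI1, 16.2 for uH2A rabbit and 8.64 for uH2A mouse with an overlap of 50% of the peak. Among peaks at or above the median height it was 11.9 for RING1A, 18.9 for BMI1 and 17.1 for uH2A mouse, and outside high-signal windows 7.36 for RING1A, 23.8 for RING1B and 17.3 for BMI1. The share of H3K27me3-dense windows with a knockdown H3K27me3 peak, 15.1%, stayed within its interval under both alternatives.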

Other observations

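The tests in this part were chosen after the results they bear on were seen. Among the tallest 25% of control peaks and outside high-signal windows, sites inside H3K27me3-dense windows were kept more often than elsewhere for 6 of the 7 antibodies, with heights not matched further. BMI1 kept 64.2% of 601 peaks in dense windows and 49.8% of 4023 elsewhere, a difference of 14.4 percentage points (10.2 to 18.5). RING1A kept 22.7% and 10.2%, RING1B 43.2% and 33.6%, uH2A mouse 32.0% and 24.7%, uH2A rabbit 74.8% and 69.3%, and EED 20.1% and 14.9% (difference 5.11 points, 1.18 to 9.55). H3K27me3 itself kept 3.96% of 4945 peaks in dense windows and 3.64% of 3601 elsewhere.

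Each of the 7 knockdown libraries had fewer peaks than its control. Lower sequencing depth alone is argued against for H3K27me3, since inside high-signal windows its peaks numbered 460 in control and 688 in knockdown cells, a ratio of 1.496 (1.33 to 1.69), with 136 and 187 kb covered, while outside the ratio was 0.101. For the other 6 antibodies the ratio inside was at most 0.875, for BMI1, and depth remains open because read totals were not used here. For EED, 11 of its 16 control peaks over 5 times the median height were taller in the knockdown library. That goes against lower depth but rests on few peaks and on heights that were not normalised. The same check gave 108 of 195 for H3K27me3. It went the other way for RING1A (7 of 240), RING1B (20 of 142), BMI1 (17 of 202), uH2A rabbit (7 of 73) and uH2A mouse (2 of 14). A lower yield of the precipitation in the knockdown cells may also account for the pattern: the ratio was lower outside than inside high-signal windows for 7 of 7 antibodies, which a loss of specific sites predicts too. A loss of H3K27me3 mainly in methylated domains would predict fewer kept H3K27me3 peaks in dense windows than elsewhere. Among the tallest 25%, with heights not matched further, the difference was 0.326 points (-0.510 to 1.13). A loss of H3K27me3 throughout the genome predicts no such difference, so this test cannot decide whether the mark was lost with the knockdown. Yield and loss of the mark cannot be told apart with 1 library per group.

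Kept peaks were often peaks of several antibodies at once. Knockdown peaks of 2 or more other antibodies lay on 60.9% of kept and 6.77% of lost EED peaks, 61.4% and 2.53% for RING1A, 81.1% and 0.791% for H3K27me3, and 90.8% and 48.0% for RING1B. Regions that give signal with any antibody would show this. Of the kept peaks of these antibodies, 7.53%, 13.1%, 26.9% and 33.0%, in that order, lay in high-signal windows. Those windows require very tall peaks and need not hold all such regions. Knockdown H3K27me3 peaks also gathered elsewhere in few places. On chromosome 9, 180 of 270 lay in the 5-Mb window from 65 Mb, against 150 of 1742 in control cells. On chromosome 14, 164 of 310 lay in that from 15 Mb, against 2 of 1741. Most kept uH2A peaks did not lie on knockdown peaks of 2 or more other antibodies. That goes against regions that give signal with any antibody as their main source, and a smaller part stays open there. The shares were 15.2% of kept and 1.38% of lost mouse peaks, and 5.73% of kept and 1.75% of lost rabbit peaks. BMI1 stood at 50.7% (49.2 to 52.2), too close to the 50% set as a bound to decide. These shares also depend on the lengths of the lists, with 7807 kept uH2A rabbit and 1065 kept RING1B peaks, and the bound does not allow for that. Polycomb sites that hold EED after the knockdown may be part of the pattern, since outside high-signal windows 15.9% of 700 kept EED peaks lay on control H3K27me3 against 4.46% of 12242 lost ones. Taller EED peaks were kept more often, and neither height nor length was matched here, so the contrast cannot decide. A first criterion, that at least 50% of kept EED peaks lie on control H3K27me3, was not met (20.5% of 757) and was replaced by this comparison of kept with lost peaks after its result was seen. Both explanations stay open, as no input or IgG library was used here.

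Chromosome 18 had more peaks per Mb before 40 Mb than after it in 14 of 14 libraries. Whether binding that depends on EED contributes to the step is not decided: the share of peaks before 40 Mb was lower in the knockdown library than in its control, with intervals apart, for 3 of the 7 antibodies, RING1A (27 peaks before 40 Mb and 8 after it in knockdown cells), BMI1 (94 and 18) and uH2A rabbit (219 and 93). That share was higher, with intervals apart, for uH2A mouse (97.0% in control and 100% in knockdown cells). All 8 of the RING1A peaks and 14 of the BMI1 peaks after 40 Mb lay before 45 Mb, and with that window left out, a recount chosen after the data were seen, the share was lower with intervals apart for uH2A rabbit alone (85.0% in control, 71.8% in knockdown) and higher for uH2A mouse (97.4% and 100%) and H3K27me3 (61.3% and 100%). A criterion used first, a knockdown share above the 51.3% expected from length with the interval apart, was met by 5 of the 7 knockdown libraries and was replaced because sites left by a partial knockdown would also meet it. The copy number of the segment could give the same direction in 14 libraries, but it was not measured here and stays open too. Its criterion, folds within 3-fold of each other, was not met. Folds ran from 1.27 for control H3K27me3 to 60.8 for knockdown EED, over the 13 libraries with any peak after 40 Mb. The knockdown EED fold rests on 1 peak there. Among control libraries the highest fold was 30.9, for uH2A mouse.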
